A study of Caenorhabditis elegans with 12 samples.

How the data were processed

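Whole-worm total RNA of Caenorhabditis elegans was profiled in 12 libraries of the laboratory strain N2 and of CN30, which the labels call transnuclear. Each strain has 3 libraries at day 0 and 1 library each at days 6, 9 and 12. The labels do not say whether the 3 day-0 libraries of a strain came from separate cultures, nor which strains gave CN30 its nucleus and its mitochondria. Sample titles write NC30 where the strain field writes CN30.

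The deposited values are FPKM, fragments scaled by gene length and by the mapped fragments of the library, which the authors computed per gene and library. A table of mRNA genes (22191 genes, of which 3167 are loci assembled from the libraries) and a table of lncRNA genes (3926 genes, of which 3792 are assembled loci) were used. The labels name HISAT, StringTie and the build WBcel235, without versions or roles. A further deposited table has other units: it lists exons, lengths in bases and positions of 9161 assembled transcripts at 7388 loci, per the file headers, with no value per sample. No read counts were used and the sequencing depth is unknown, so no counting interval can be given. Gene symbols and positions come from the WBcel235 annotation; assembled loci are written MXLOC or LXLOC as in the tables, with the annotated genes they overlap.

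Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). Genes entered a fit with at least 1 FPKM (mRNA) or 0.5 FPKM (lncRNA) in at least 3 of its libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and are two-sided. CN30 was compared with N2 at day 0 (3 against 3 libraries) and at days 6 to 12 (3 pairs, with day as a factor). Days 6 to 12 were compared with day 0 within each strain (3 against 3). The product of strain and age class was tested over all 12 libraries. Day 9 against day 6 and day 12 against day 9 were tested over all 12 libraries with strain as an additive term, for mRNA only. An exact permutation test of 3 against 3 cannot go below p = 0.1, so each call rests on the spread that limma pools across genes.

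A set of 40 gene lists was written before the data were examined. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The list of protein genes of the mitochondrial genome had 0 tested members and the male markers too few, which left 38 lists. Members were counted with p adjusted over all genes and adjusted over the list alone.

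Named genes follow a rule set before the data were examined. Per mRNA comparison these are the 8 largest falls and 8 largest rises among genes with adjusted p under the threshold, at least 5 FPKM in the higher group and no overlap between the groups. For pairs of ages the same sign in all 3 was needed, and for the interaction the same shift in all 3. Up to 4 members of each list with the smallest p were added, and the pair peel-1 and zeel-1. For lncRNA these are the 4 largest in each direction at 1 FPKM or more, and between later ages the 5 largest in each direction. Genes with a group at 0 in every library are described as listed at 0; where a fitted interaction of such a gene is printed, it depends on the pseudocount and is no fold. Of the mRNA genes, 21 were listed at 0 in all 6 day-0 libraries with 5 FPKM or more in all 6 later ones, and 26 the other way round. One of the latter is mev-1, a respiratory chain subunit that every cell uses, so an exact 0 can be a missing estimate. Of these 47 genes 45 overlap an assembled locus on the same strand, against 22.9% of the 13066 annotated genes in the interaction fit, a count made after the values were seen.

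Alternatives were a pseudocount of 0.1, no filter, quantile normalization, median-ratio rescaling, robust shrinkage, the replicate number as a block, no day term, linear day or day as a factor, a joint fit of all 12 libraries, and each library left out in turn. Leaving out both day-6 libraries was added after seeing the data. The pipeline was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale per mRNA comparison. It recovered 54 to 80% of the former and 87 to 96% of the latter, with 4.12 to 6.91% of calls false. For lncRNA, with 28 to 60 genes changed by each size, it recovered 65 to 100% of the smaller changes except in the interaction, where it recovered 7.14% of them and 85.7% of the larger, and the share of false calls reached 12.8%. The simulated noise was independent between genes, and changed genes were taken only from those with fitted log2 levels above 2. Most genes were left unchanged, unlike in the real age comparisons. These rates thus leave out errors that genes of a library share, and low genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.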

Results

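The series measured mRNA and lncRNA of whole worms of N2 and of the transnuclear strain CN30 as they aged, to relate mitochondrial polymorphisms and age to the transcriptome. Each strain had 3 libraries at day 0, and 1 library at each of days 6, 9 and 12. Summed mRNA FPKM lay between 874694 and 911271 at day 0 and between 726252 and 779302 later. Between 11831 and 14395 mRNA genes reached 1 FPKM in a library. The depth is unknown.

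Age parted the libraries first: component 1 of the mRNA values held 82% of the variance over 15719 genes, with all day-0 libraries on one side. Component 2 held 6.45%. On it the N2 libraries of days 6 and 9 stood at 52.91 and 46.03, whereas N2 day 12 stood at -3.50, nearer to the later CN30 libraries at -14.70, -33.72 and -49.76. At day 0, N2 replicate 2 stood apart, at 31.91 against 1.33 and -2.40 for the other N2 libraries. Relative to those, its cuticle collagens had a median log2 deviation of -1.27, its moulting genes -1.22 and its vitellogenins, the yolk protein precursors, 2.14.

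**Figure D1:**
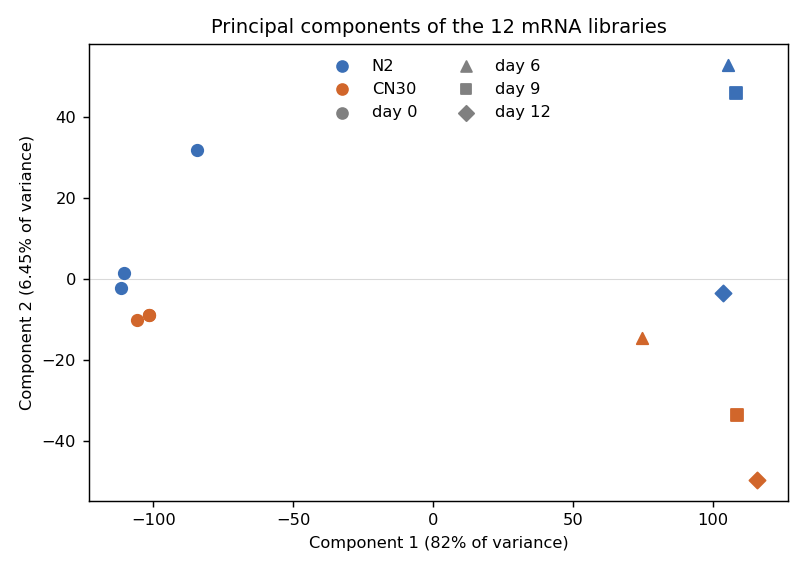
Each point is one mRNA library on components 1 and 2 of log2(FPKM + 1), with colour for strain and shape for day. Day-0 libraries lie left and later ones right, and N2 day 12 lies at -3.50 on component 2, below N2 days 6 and 9.

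The comparison of the strains at day 0 asked what differed on the first day sampled. The Argonaute gene ppw-1 (I, 4185174 to 4189935), which acts in germline RNA interference, had 91.5 ± 0.243 FPKM in N2 and 6.90 ± 1.04 in CN30 (SD, n = 3 each), a log2 difference of -3.56 ± 0.11 (SE, adjusted p = 0.000126). The assembled locus MXLOC_000398 over it had 38.32 to 43.60 FPKM in N2 and 43.13 to 45.73 in CN30 and did not pass (0.13 ± 0.07, adjusted p = 0.325), so how reads were shared between ppw-1 and this locus limits the size of the difference. The neighbours fbxa-206 and Y102A5C.2 (V, 16917192 to 16919786) had 13.8 ± 1.52 and 15 ± 0.390 FPKM in N2 against 0.30 ± 0.170 and 0.193 ± 0.0723 in CN30. T16G12.3 and ecps-2 had 28.7 ± 6.76 and 9.91 ± 1.17 FPKM in N2 and were listed at 0 in all 3 CN30 libraries. MXLOC_008216, which overlaps T16G12.3, had 3.86 to 4.26 FPKM in CN30 and 17.76 to 23.09 in N2. It was thus lower in CN30 as well (log2 -2.09). The assembled locus MXLOC_020436 (X, 11199476 to 11202442), which overlaps the collagen genes col-178 and col-179, had 1663 ± 136 FPKM in CN30 and 2.63 ± 2.88 in N2. The annotated gene col-178 itself went the other way, with 416 ± 24.3 FPKM in CN30 and 2413 ± 1299 in N2 (log2 -2.41 ± 0.34, adjusted p = 0.0165). The 2 mirror each other on the same strand, so reads given to one or the other are not told from a difference in expression.

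Among gene families at day 0, the C-type lectins, many of them induced by microbes, held 26 that were higher in CN30, 1 lower and 70 that did not pass of 97 tested, and 42 rose and 6 fell adjusted over the list alone. Examples are clec-197, with 10.2 ± 3.64 FPKM in CN30 and 0.123 ± 0.112 in N2, and clec-207, with 8.41 ± 3.13 against 0.0133 ± 0.0231. Their camera adjusted p was 1.74e-05, and adjusted p = 0.84 with an estimated correlation. Of 3 neighbouring catalase genes, ctl-1 was lower in CN30, at 6.18 ± 1.60 FPKM against 23.9 ± 4.22 in N2 (log2 -1.81 ± 0.21, adjusted p = 0.0084), ctl-3 had 4.70 ± 2.71 and was listed at 0 in all 3 N2 libraries, and ctl-2 had 24.9 ± 5.28 against 8.95 ± 3.63 and did not pass (adjusted p = 0.0538). MXLOC_007021, over ctl-1, ctl-2 and ctl-3, had 41.69 to 45.08 FPKM in CN30 and 33.62 to 61.18 in N2 and did not pass (adjusted p = 0.641), so reads shared among these genes are not told from a change of ctl-1. Of 62 histone genes, 8 rose and 3 fell, among the falls his-48, with 329.6 ± 66.6 FPKM in CN30 and 966 ± 141 in N2. Of 33 proteasome genes 1 fell, rpt-6, with a list median of -0.12 (camera adjusted p = 3.13e-07, adjusted p = 0.607 with an estimated correlation). Of the 61 nuclear genes for respiratory chain subunits 0 passed in limma, adjusted over all genes or over the list alone, with 8 at an unadjusted p under 0.05. The sperm-borne toxin gene peel-1, which the wild isolate CB4856 lacks, was present in both strains, between 3.47 and 9.21 FPKM in N2 and between 4.77 and 6.27 in CN30. Its pair zeel-1 had 0 to 0.02 FPKM in the day-0 libraries of both strains, too little to tell them apart. Later it had 0.23 to 1.4 FPKM in N2 and 1.01 to 1.55 in CN30.

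In all, 529 of 14380 mRNA genes differed at day 0, 297 higher and 232 lower in CN30, and 4431 genes had no overlap between the strains, where chance gives 10%. Without N2 day-0 replicate 2, the library that stood apart, 1753 genes passed (844 higher, 909 lower), without N2 replicate 1, 154 (111 higher, 43 lower), and without N2 replicate 3, 429, of which 306 were higher. Without CN30 replicate 1, 2 or 3, 81, 82 or 86 passed, and the balance turned, with 30, 25 and 24 higher and 51, 57 and 62 lower. In each of these 3 fits 114 of the 297 higher calls and 0 of the 232 lower ones were not tested. Their genes no longer reached 1 FPKM in 3 libraries, so the filter made part of the turn. Without any one N2 replicate, 36 of the 232 lower calls were not tested. Quantile normalization gave 839, of which 38.1% were higher in CN30 against 56.1% in the analysis above, and median-ratio rescaling 301 higher and 339 lower. With the replicate number as a block 158 passed, though deviations of libraries that share a number had correlations across genes of only 0.045, -0.04 and -0.015, and genes are not independent replicates.

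At days 6 to 12 the same loci on chromosomes I and V set the strains apart. The gene ppw-1 had 194 ± 20.6 FPKM in N2 and 9.12 ± 8.26 in CN30 (SD over the 3 ages, n = 3), and fbxa-206 had 45.5 ± 3.39 against 2.65 ± 4.57. MXLOC_001250, which overlaps C27C7.1, had 122 ± 25.6 FPKM in N2 and 4.59 ± 2.51 in CN30 (log2 -4.53 ± 0.19, adjusted p = 0.0116). MXLOC_008075 (III, 8852069 to 8868193), over the mating plug gene plg-1, had 36.8 ± 3.15 against 2.93 ± 4.85. The small heat shock gene hsp-12.3 was higher in CN30, at 43.8 ± 12.3 FPKM against 4.26 ± 1.87 (log2 3.13 ± 0.16, adjusted p = 0.0173). MXLOC_020436 had 115 ± 137 FPKM in CN30 against 0.443 ± 0.404, with the limit given for day 0.

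**Figure D2:**
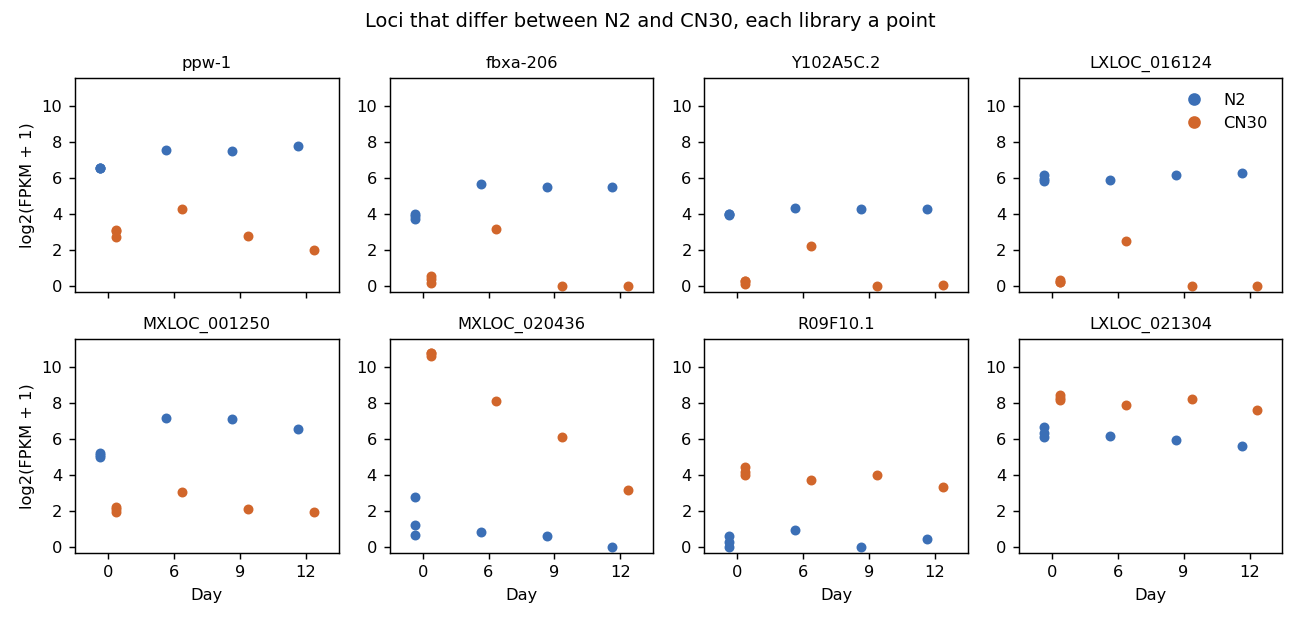
Each panel shows log2(FPKM + 1) of one locus by day, each point a library (3 per strain at day 0, 1 later). At ppw-1, fbxa-206, Y102A5C.2, LXLOC_016124 and MXLOC_001250 every N2 library lies above every CN30 library, and CN30 day 6 is the highest of the CN30 libraries; at MXLOC_020436, R09F10.1 and LXLOC_021304 every CN30 library lies above every N2 library, and at MXLOC_020436 reads shared with col-178 limit this.

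Of 33 oocyte and maternal genes, 16 fell in later CN30 worms against N2, 1 rose and 16 did not pass, and 25 fell adjusted over the list alone. The oocyte pseudophosphatase gene egg-5 had 118 ± 13 FPKM in CN30 and 205.8 ± 20.1 in N2, and puf-6 74.7 ± 11.4 against 127 ± 11.6. Their camera adjusted p was 2.69e-11, and adjusted p = 0.758 with an estimated correlation. Of 26 autophagy genes 5 rose and none fell, among them sqst-1, the autophagy receptor, with 157 ± 71.1 FPKM in CN30 and 66.9 ± 34.1 in N2 (camera adjusted p = 0.0152, adjusted p = 0.758 with an estimated correlation). Of 15 neuron markers 6 rose, among them unc-13, which acts in transmitter release, with 5.55 ± 1.52 FPKM against 1.93 ± 0.174 (camera adjusted p = 0.000604, adjusted p = 0.758 with an estimated correlation). Of 65 mitochondrial ribosomal protein genes 5 fell, among them mrpl-20, with 65.4 ± 9.02 FPKM against 91.4 ± 9.31; 0 fell adjusted over the list alone (camera adjusted p = 8.13e-08, adjusted p = 0.758 with an estimated correlation). Cuticle collagens stood at a median of 6.52% of their day-0 level in the CN30 day 6 library, against 1.41% in N2 day 6, and major sperm protein genes at 5.02% against 0.359%. At day 9 collagens stood at 1.21% in CN30 against 1.66% in N2 and major sperm protein genes at 0.532% against 0.119%, and at day 12 at 0.319% against 2.96% and 0.75% against 2.1%.

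In all, 1690 of 13015 genes differed at days 6 to 12, 1272 higher and 418 lower in CN30. This count was not stable: in limma it was 0 without N2 day 9 or without CN30 day 9 (2931 and 2783 at an unadjusted p under 0.05), 25 without N2 day 6 (10 higher, 15 lower), 30 without CN30 day 6 (9 higher, 21 lower), 1050 without N2 day 12 (175 lower), 930 without CN30 day 12 (179 lower), 9 without both day-6 libraries (chosen after seeing the data), 2 without a filter and 134 without the day term. The fit pairs libraries by day, so a library left out takes its partner out of the strain estimate. Fits without a later library thus rest on fewer pairs and fewer residual degrees of freedom, which can lower counts. Leaving out N2 day 6, CN30 day 6 or both drops the same pair, so these are not separate checks. Of 11806 genes tested at both times, 65 were higher in CN30 at both, where 17.8 were expected of independent calls, 52 were lower at both (4.89 expected), and 12 and 6 changed sign. Quantile normalization gave 873 genes with 62.8% higher in CN30, and median-ratio rescaling 60.1%, against 75.3% in the analysis above. Fewer genes at 0 in later CN30 libraries, described below, also limit this excess of higher calls.

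In N2, cuticle, sperm and muscle transcripts fell from day 0 to the later days. Collagen and sperm genes fell while oocyte genes rose, as given below, so maturation after day 0 is not told from ageing. FPKM are scaled to the whole library, so a larger share of one tissue can lower the values of others. Neither was tested. This limit holds for every comparison with day 0 and for the interaction, in both strains and for lncRNA. The collagen gene col-7 fell from 681 ± 180 FPKM at day 0 to 0.617 ± 0.654 later (SD, n = 3 each), and col-146 from 660 ± 37 to 0.85 ± 0.685. Of 128 cuticle collagens 6 rose, 18 did not pass and the rest fell. All 28 major sperm protein genes fell, among them msp-57, from 381 ± 49.9 to 2.35 ± 2.37 FPKM, and 54 of 59 other sperm genes fell. Of 22 body-wall muscle genes 21 fell, among them mup-2, a troponin T gene, from 553 ± 30.6 to 29.7 ± 1.28 FPKM. Transcripts that rose include mtl-1, a metallothionein gene, from 0.270 ± 0.311 to 83.4 ± 20.5 FPKM, and clec-266, from 0.247 ± 0.219 to 130.3 ± 89.3.

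Of 73 cytosolic ribosomal protein genes 70 fell and none rose, with a median of -0.57, and of 60 nuclear respiratory chain genes 48 fell and 3 rose, among them asb-2, an ATP synthase subunit gene, from 547 ± 33 to 132 ± 21.3 FPKM. Of 33 oocyte genes 31 rose, among them egg-2, from 43.5 ± 4.69 to 221 ± 26.5 FPKM, and of 29 replication genes 28 rose, among them mcm-5, a helicase subunit gene, from 65.0 ± 2.21 to 211 ± 7.99. Of 65 histone genes 41 rose and 4 fell. Camera adjusted p for these 5 lists lay between 6.45e-11 and 0.000324, and adjusted p lay between 0.446 and 0.572 with an estimated correlation; for the collagen, major sperm protein, other sperm and muscle lists camera adjusted p lay between 1.11e-14 and 9.45e-09, and adjusted p was 0.446, 0.518, 0.446 and 0.116 with an estimated correlation.

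In all, 10269 of 14129 genes changed in N2, 5749 up and 4520 down. Without day-0 replicates 1 or 3, 2323 and 2307 were down and the median of all genes was 0.37 and 0.41; of the 4520 falls 1656 were then not tested, since their genes no longer reached 1 FPKM in 3 libraries. The median of all genes was 0.14 on the log2 scale, 0.30 under quantile normalization and -0.09 under median-ratio rescaling, where 4853 of the called genes were up and 5311 down. The proteasome genes turned direction, with 16 up and 4 down here and 4 up and 6 down under median-ratio rescaling. For a list near that shift this largely follows from the rescaling of whole libraries.

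In CN30 much the same genes changed over these days. Of 13866 genes tested in both strains, 5336 rose in both, where 2662 were expected of independent calls, and 3933 fell in both (1510 expected); 2 and 14 went opposite ways. The log2 changes had r = 0.945 across genes, which are not independent replicates, and the fits share no library. The collagen gene col-62 fell from 760.3 ± 13.9 to 4.51 ± 6.39 FPKM, and col-120 had 518 ± 60.2 FPKM at day 0 and was listed at 0 in all 3 later libraries, where the assembled locus MXLOC_012978 over it had 32.25 to 40.57 FPKM. The caveolin gene cav-1 rose from 2.68 ± 0.771 to 429 ± 58.1 FPKM, ule-1 from 7.23 ± 0.322 to 711 ± 122.5, and the lysozyme gene ilys-3 from 0.417 ± 0.163 to 101 ± 43.4.

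By group in CN30, 122 of 136 cuticle collagens fell and 7 rose, all 28 major sperm protein genes fell, and 72 of 74 ribosomal protein genes fell. Of 61 nuclear respiratory chain genes 54 fell and 1 rose. Of 33 oocyte genes 31 rose, of 29 replication genes 28 rose, and of 26 autophagy genes 24 rose, among them epg-2, from 6.77 ± 0.129 to 57.8 ± 7.05 FPKM. Of the C-type lectins 63 fell, 16 rose and 23 did not pass. Of 186 F-box and BATH genes 120 rose and 35 fell. Camera adjusted p lay between 4.94e-13 and 0.000819 for these 9 lists, and adjusted p lay between 0.553 and 0.718 with an estimated correlation. In all, 12191 of 15069 genes changed, 6937 up and 5254 down. Without day-0 replicates 1, 2 or 3, 3447, 3395 and 3420 were down and the median of all genes was 0.41, 0.42 and 0.40, with 1473 or 1474 of the 5254 falls not tested for the same reason. The median was otherwise 0.24, and -0.01 under median-ratio rescaling, where proteasome genes had 1 up and 12 down against 12 up and 0 down here. The ribosomal protein gene rps-24 fell by 0.68 on the log2 scale, but had 0.03 under quantile normalization.

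**Figure D3:**
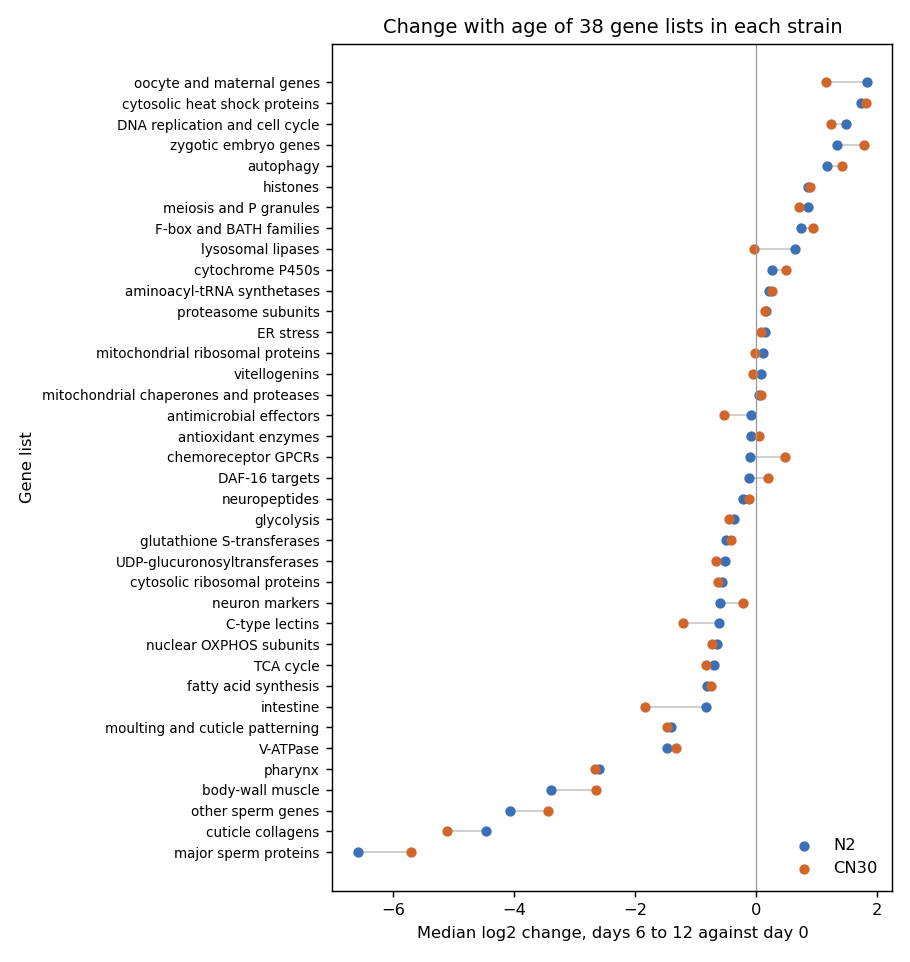
Each row is one of 38 gene lists; points are the median log2 change of its tested members from day 0 to days 6 to 12 in N2 and in CN30. Major sperm protein genes lie lowest, at -6.58 in N2 and -5.71 in CN30, and oocyte genes highest in N2, at 1.83 against 1.15 in CN30; medians near 0 turn sign under other scalings, as for the proteasome genes.

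Whether the change from day 0 to days 6 to 12 differed between the strains was tested directly. The heat shock gene hsp-12.3 had 8.10 ± 3.02 FPKM at day 0 and 4.26 ± 1.87 later in N2, and 13.6 ± 1.53 and 43.8 ± 12.3 in CN30, an interaction of 2.39 ± 0.48 on the log2 scale (adjusted p = 0.0363). The lysozyme gene ilys-3 reached 11.8 ± 4.09 FPKM later in N2 and 101 ± 43.4 in CN30 (2.64 ± 0.42, adjusted p = 0.0159). T16G1.4 had 6.21 ± 1.89 and 7.14 ± 1.09 FPKM in N2 and 1.82 ± 0.358 and 26.1 ± 12.62 in CN30. The lectin gene clec-9 rose in N2, from 0.050 ± 0.0361 to 26.6 ± 17.1 FPKM, and stood at 0.0133 ± 0.0231 and 1.01 ± 0.312 in CN30 (-3.54 ± 0.52, adjusted p = 0.0115). Y54G11A.2 was listed at 0 in all 3 later CN30 libraries and had 15.67, 14.04 and 13.94 FPKM in N2 of days 6, 9 and 12. The assembled locus MXLOC_005085 over it had 38.14 to 81.78 FPKM in all libraries, so this 0 can be a missing estimate.

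Of 33 oocyte genes 3 had a lower interaction, egg-2, egg-3 and egg-4, and 30 did not pass; 12 were lower adjusted over the list alone (median -0.52, camera adjusted p = 3.28e-08, adjusted p = 0.928 with an estimated correlation). Of 110 C-type lectins 9 had a lower interaction and none a higher one (camera adjusted p = 8.78e-05, adjusted p = 0.928 with an estimated correlation). Among them clec-158, clec-261 and clec-92 were too low in N2 to show a fall. Their N2 means were 0.07, 0 and 0.0133 FPKM at day 0, and 0.0633, 0.0267 and 0.06 later. In CN30 they fell, from 2.82, 1.51 and 5.36 FPKM to 0.217, 0.297 and 0.463. For these genes the interaction thus cannot be told from the strain difference at day 0. The rise of clec-9 in N2 does not stand for them. The body-wall muscle gene act-4 kept more of its level in CN30, at 1498 ± 117 and 314.5 ± 52.0 FPKM against 1736 ± 225 and 165 ± 16.3 in N2. In all, 315 of 15719 genes had an interaction, 181 higher and 134 lower. Single libraries decided this count: 2025 without N2 day 12, 1035 without N2 day-0 replicate 2, 709 without CN30 day 6, 58 without N2 day-0 replicate 1 (28 higher, 30 lower), 49 higher and 55 lower without N2 day-0 replicate 3, 79 and 118 without N2 days 6 and 9, 74, 61 and 78 without CN30 day-0 replicates 1, 2 and 3, 93 without CN30 day 9, and 67 higher and 52 lower without CN30 day 12. It was 205 without both day-6 libraries (chosen after seeing the data), 194 with a pseudocount of 0.1, 552 under median-ratio rescaling and 1883 with day as a factor.

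Between later ages few genes passed. Genes that fell from day 9 to day 12, with strain as an additive term, include lys-2, a lysozyme gene, from 59.99 to 5.14 FPKM in N2 and from 39.58 to 5.76 in CN30 (log2 -2.95 ± 0.46, adjusted p = 0.0355), and dod-24, a DAF-16 target gene, from 91.47 to 10.43 and from 45.45 to 6.92 (-2.78 ± 0.41, adjusted p = 0.0251). Of 63 antimicrobial effector genes 6 fell and 57 did not pass, and 23 fell adjusted over the list alone (camera adjusted p = 1.97e-20, adjusted p = 0.0697 with an estimated correlation). In all 52 genes passed, 6 up and 46 down; the count was 27 under median-ratio rescaling, and without single libraries it went as low as 10 (N2 day 9) and 12 (N2 day 12) and as high as 175 (CN30 day 9) and 84 (N2 day-0 replicate 2), with 32, 22, 15 and 30 without N2 day-0 replicate 3, CN30 day-0 replicates 1 and 3 and CN30 day 12, and 6 up and 30 down without CN30 day-0 replicate 2. From day 6 to day 9, 4 genes rose and none fell in limma, with 639 at an unadjusted p under 0.05. The cell death regulator gene ced-9 was listed at 0 in all day-0 libraries and in N2 day 6, and had 6.81 FPKM in N2 day 9 and 6.78 in CN30 day 9. It overlaps the assembled locus MXLOC_008250, which also covers mev-1 and had 49.53 to 106.22 FPKM in all 12 libraries, so a share of reads given to one or the other locus is not told from a change of ced-9. The count was 63 without N2 day 6 (7 up, 56 down), 14 without N2 day 9 (7 up, 7 down) or CN30 day 6, 2 without CN30 day 9 or any single day-0 library, and 8 with a pseudocount of 0.1.

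Among lncRNA, a pair of loci near fbxa-206 marked N2 at day 0. LXLOC_016124 (V, 16928257 to 16930126) had 63.0 ± 7.64 FPKM in N2 and 0.213 ± 0.0611 in CN30 (log2 -5.72 ± 0.15, adjusted p = 3.04e-07), and LXLOC_018967 (V, 16924878 to 16927584) had 22.9 ± 2.1 against 0.00333 ± 0.00577. LXLOC_021304 on X was higher in CN30, at 313 ± 35.1 FPKM against 82.0 ± 15.2. In all 117 of 1116 lncRNA genes passed at day 0, 80 higher and 37 lower in CN30. Without a filter 57 passed, and without N2 replicates 1 or 3 or CN30 replicates 1, 2 or 3, 46, 62, 47, 34 and 46, with 36, 48, 28, 16 and 23 of these higher. Of the 80 higher calls 34 were not tested without any one CN30 library, and of the 37 lower calls 12 without any one N2 library. These genes no longer reached 0.5 FPKM in 3 libraries, so the filter made part of the shift. Under quantile normalization 47.3% and under median-ratio rescaling 47.2% were higher, against 68.4% in the analysis above.

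At days 6 to 12 the same pair on chromosome V differed, with LXLOC_016124 at 68.4 ± 9.39 FPKM in N2 and 1.59 ± 2.73 in CN30. The neighbours LXLOC_005459 and LXLOC_005458 on II were higher in CN30, at 16.9 ± 8.08 and 18.7 ± 9.61 FPKM against 1.61 ± 1.46 and 2.21 ± 1.75. In all 227 of 1140 genes passed, 209 higher and 18 lower. Over 1215 antisense loci the median level was 0.18, 0.29 and 0.56 FPKM in CN30 at days 6, 9 and 12, against 0.05, 0.05 and 0.15 in N2. The median of all tested lncRNA was 0.27, and 0.02 under median-ratio rescaling, where 95 passed and 61.1% were higher, against 92.1% here; quantile normalization gave 56 with 60.7% higher. The count was 27 without a filter, 105 without the day term, 139 without both day-6 libraries (chosen after seeing the data), 120 without CN30 day 9, and 137 higher and 19 lower without CN30 day 6. Of the 209 higher calls, 69 were not tested without CN30 day 9 and 65 without CN30 day 6. Their genes no longer reached 0.5 FPKM in 3 libraries. A library left out here also takes its partner out of the strain estimate, as for mRNA.

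With age the locus LXLOC_021257 (X, 1504135 to 1505156), which overlaps tts-1, a lncRNA known from long-lived worms, rose from 4.63 ± 2.74 to 1507 ± 247 FPKM in N2 and from 7.23 ± 1.56 to 1264 ± 289 in CN30 (log2 8.20 ± 0.40 and 7.26 ± 0.26). LXLOC_012528, which overlaps the sperm genes nspd-3 and nspd-6, fell from 104.4 ± 22.4 to 0.837 ± 0.698 FPKM in N2 and from 92.4 ± 9.61 to 1.30 ± 1.37 in CN30. In N2 374 of 917 lncRNA genes passed, 122 up and 252 down (32.6% up, and 58.1% under quantile normalization), and 157, 223 and 179 without day-0 replicates 1, 2 and 3, of which 76, 101 and 92 were up. Without days 6, 9 or 12, 68, 60 and 65 were up and 211, 207 and 253 down. Of the 252 falls 130 were not tested without any one day-0 library, and of the 122 rises 46 or 47 without any one later library. In CN30 681 of 1338 passed, 349 up and 332 down; the count was 413 and 415 without day-0 replicates 1 and 3 (253 and 260 up), and 305 up and 150 down without replicate 2, with 156 of the 332 falls not tested. Without single later libraries 183 of the 349 rises were not tested, and the counts were 101 up and 292 down without day 9 (393 in all), 141 up and 305 down without day 12 (446) and 209 up and 327 down without day 6. Of 834 tested in both, 88 rose and 182 fell in both strains, where 24.8 and 64.3 were expected of independent calls.

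The lncRNA interaction passed at 8 of 1717 genes, 6 higher and 2 lower, among them LXLOC_012222, with 2.94 ± 0.484 FPKM at day 0 and 0.140 ± 0.121 later in N2, and 0.0633 ± 0.110 at day 0 and listed at 0 in all 3 later libraries in CN30. LXLOC_012222 was too low in CN30 at day 0 to show a fall, so its interaction cannot be told from the strain difference at day 0. The count was 133 without N2 day 12 and 100 without CN30 day 6, and 2 and 4 without N2 days 6 and 9. In limma it was 0 without N2 day-0 replicate 1 (269 at an unadjusted p under 0.05), 2 without N2 day-0 replicate 3, 2, 2 and 5 without CN30 day-0 replicates 1, 2 and 3, and 3 and 2 without CN30 days 9 and 12. It was 4 with a pseudocount of 0.1, 2 without a filter or with robust shrinkage, 5 under quantile normalization, 120 with day as a factor and 23 without both day-6 libraries (chosen after seeing the data).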

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

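The tests weighed here were chosen after the results were seen, except that on gna-2. A difference between the strains in their response to age was tested as an interaction, and 315 mRNA genes and 8 lncRNA genes passed. Among mRNA genes the largest interactions on the log2 scale were -4.57 (Y54G11A.2), -3.74 (spp-9), -3.61 (npp-2), -3.54 (clec-9), -3.42 (C49G7.13), -3.36 (F56D6.11), -3.18 (F13D12.5) and -3.08 (K09F6.7), and 6.40 (ZK632.9), 3.51 (B0001.5), 3.39 (abf-4), 3.14 (Y69A2AR.32), 2.97 (T16G1.4), 2.93 (MXLOC_010359), 2.93 (F26A3.4) and 2.91 (Y50E8A.5). All but clec-9, abf-4, T16G1.4, MXLOC_010359 and F26A3.4 have a group listed at 0 in every library, so their fitted values depend on the pseudocount and are neither folds nor bounds. Of the 15 that are annotated genes, 10 overlap an assembled locus, npp-2 and Y54G11A.2 among them, so reads given to one or the other locus are not told from a change. Among lncRNA they were -1.12 (LXLOC_021123), -0.89 (LXLOC_008334), 1.71 (LXLOC_012222), 1.65 (LXLOC_008192), 1.51 (LXLOC_018575) and 1.41 (LXLOC_004848). LXLOC_012222 has a group listed at 0, with the same limit. LXLOC_012222 in CN30 and LXLOC_008334 in N2 had day-0 means of 0.0633 and 0.19 FPKM, too low to show a fall. Their interactions thus cannot be told from the strain difference at day 0.

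Of the named list members 25 passed in the interaction. Lists past the camera threshold had median interactions of -0.52 (oocyte genes), -0.23 (replication), -0.43 (C-type lectins), -0.14 (mitochondrial ribosomal proteins), 0.51 (other sperm genes), 0.59 (body-wall muscle), -0.20 (meiosis), 0.42 (neuron markers) and -0.69 (intestine). None of these 9 held in camera with an estimated correlation (lowest adjusted p = 0.928) or in fry. With 100 random splits of the 12 libraries, 1 gave as many mRNA genes as the real one, the real one itself, with a highest other of 281 against 315. Of all 80 splits that keep the later days as pairs, 2 gave 315 or more: the real one, and one with 1667 that swaps the strains at every later day and so counts the strain difference itself, a structure of the samples. The next highest was 116. These splits relabel the strains within each age class, so most of them also break up the strain difference itself. That difference then adds to the spread of those fits and can lower their counts. The splits thus cannot exclude chance for the interaction. They were not repeated under the alternatives, and the real count was 58 without N2 day-0 replicate 1. For lncRNA 6 of 100 gave 8 or more, with a highest of 29, and 6 of 80 with a highest of 283, from the same swap of the strains, and 25 without it. The splits with 281 and 29 both keep day 0 and set N2 day 6, N2 day 9 and CN30 day 6 against the other later libraries, with opposite labels. For gene lists 95 of 100 gave 9 or more, with a highest of 25, and 75 of 80 with a highest of 22 and a lowest of 6, so chance is not excluded for lncRNA or lists either. Splits with several times the real count point to a structure of the samples, whose cause was not tested.

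For the comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real counts of mRNA genes, 529, 1690, 10269 and 12191, and of lncRNA genes, 117, 227, 374 and 681, were each reached by 1 split, the real one, and the highest other split gave 0. For gene lists, 2 splits reached the real 17 at day 0 (highest other 20), 5 the real 17 at days 6 to 12 (23), 9 the real 20 in N2 (28) and 9 the real 22 in CN30 (25). The fit at days 6 to 12 pairs the libraries by day, which most of its 10 splits do not; only 4 splits do, again too few. Of these, 1 reached the real 1690 mRNA genes and 1 the real 227 lncRNA genes, the real one each time (highest other 0 in limma, with up to 316 and 32 at an unadjusted p under 0.05), and 3 reached the real 17 lists (highest other 23).

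The CN30 day 6 library holds transcripts that otherwise mark N2: at 8 loci high in every N2 library and under 5% of the N2 mean in the other CN30 libraries, it stood at a median of 9.89% of N2 day 6, from 4.73 to 18.6%. At T16G12.3 it had 0.80 FPKM, but CN30 day 12 had 0.87. At MXLOC_001250 it had 7.47 FPKM, and the other CN30 libraries had 2.92 to 3.63. These loci, at 5.29 and 5.35% of N2 day 6, thus hold signal of CN30 itself, and they weigh on the lower quartile used next. Later N2 worms or their RNA in this sample may account for the transcripts that mark N2: the upper quartile of the share of N2 day 6 was 2.93 times the lower, and 3.17 times against N2 at day 0. Young worms of either strain would bring transcripts of day 0, and major sperm protein, other sperm, collagen and moulting genes stood at medians of 5.02, 5.4, 6.52 and 9.18% of day 0, against 0.359, 0.498, 1.41 and 4.34% in N2 day 6, which later N2 worms alone would not bring. Against the day 0 source, ZK632.9 and Y69A2AR.32, at 32.02 to 110.06 and 5.79 to 10.63 FPKM in N2 at day 0 and at 0 in later N2, were listed at 0 in CN30 day 6, but MXLOC_009732 and MXLOC_010362 over them had 167.94 and 22.77 FPKM there, so these 0s can be missing estimates. The sources thus cannot be told apart, with bounds set after both ratios had been seen, and expression in CN30 itself at day 6 stays open and untested.

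N2 day-0 replicate 2 stands apart from the other N2 day-0 libraries, and 1753 genes passed at day 0 without it. Older worms mixed into it would lower sperm transcripts as much as collagens, since both are nearly gone later; the median deviation of major sperm protein genes was 0.32 and that of collagens -1.27. Worms further along the last larval stage could give less collagen and more yolk transcript. In a test set before its value was seen, the eggshell gene gna-2 deviated by 0.13, a single gene and too small to decide. Outside that test, oocyte and maternal genes deviated by a median of 0.489 and replication genes by 0.165, and the question stays undecided. A difference between groups of the design was not tested, since the labels give these libraries one group.

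Antisense loci carried more low-level signal in later CN30 libraries: over 1215 loci the median was 0.18, 0.29 and 0.56 FPKM at days 6, 9 and 12, against 0.05, 0.05 and 0.15 in N2. Wrong-strand reads of the host gene would follow its level, but the highest Spearman rho across loci, which are not independent replicates, was 0.039. Lower depth would leave more loci at 0, yet the share at 0 was lower than in N2 by at least 16.3 points. Genomic DNA may contribute: the share of silent genes of 1 exon at 0 was lower by at least 10.7 points at each age, although their median rise was 0 FPKM at each age, a first measure that the many genes listed at 0 hold at 0 and that the share replaced after it was seen. A difference by strain and age stays open and untested, and the higher lncRNA levels of later CN30 libraries carry this limit.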

How the results depend on the processing

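Leaving out both day-6 libraries was chosen after seeing the data; the other alternatives were set before. Counts of mRNA genes at day 0 went from 529 to 839 under quantile normalization and to 158 with the replicate number as a block. Counts at days 6 to 12 went from 1690 to 2 without a filter, 873 under quantile normalization, 134 without the day term and 9 without both day-6 libraries. Interaction counts went from 315 to 194 with a pseudocount of 0.1, 552 under median-ratio rescaling, 1883 with day as a factor and 205 without both day-6 libraries. From day 6 to day 9 the count went from 4 to 8 with a pseudocount of 0.1, and from day 9 to day 12 from 52 to 27 under median-ratio rescaling. For lncRNA the day-0 count went from 117 to 57 without a filter. At days 6 to 12 it went from 227 to 27 without a filter, 56 under quantile normalization, 95 under median-ratio rescaling, 105 without the day term and 139 without both day-6 libraries. The lncRNA interaction went from 8 to 4 with a pseudocount of 0.1, 2 without a filter, 5 under quantile normalization, 2 with robust shrinkage, 120 with day as a factor and 23 without both day-6 libraries. Of 129 list calls, 0 held with an estimated correlation, and fry gave 60.

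Leaving out each library in turn gave 81 to 1753 mRNA genes at day 0, 0 to 1050 at days 6 to 12, 7526 to 9823 with age in N2, 9852 to 11711 with age in CN30, 58 to 2025 for the interaction, 2 to 63 from day 6 to day 9 and 10 to 175 from day 9 to day 12. For lncRNA it gave 34 to 146, 120 to 326, 157 to 318, 393 to 536 and 0 to 133 in the order of the first 5. At days 6 to 12 each of these fits loses a whole pair, so its count can fall through lost residual degrees of freedom. A single library left in a group is assumed to vary like the others. Among values of named genes that passed in the main or the alternative fit, 1 turned direction. This was rps-24 with age in CN30, at 0.028 under quantile normalization. Of the other values of named genes under the alternatives, 9540 kept their direction and side of the threshold, 1634 lost the call and 277 gained it. A further 32 turned direction without passing in either fit. The cause of these shifts was not tested, and the unknown depth leaves the error of low values open.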

Other observations

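The tests on genes that differ at every age, and the choice of LXLOC_000002, came after the values were seen. The mitochondrial genome had no mRNA genes of its own in the tables, but one lncRNA locus, LXLOC_000001, spans most of its plus strand (859 to 13235). It had 1544 ± 505 FPKM in N2 and 1994 ± 958 in CN30 at day 0 (SD, n = 3), with a log2 difference of 0.33 ± 0.37 (SE, adjusted p = 0.641), and 0.42 ± 0.27 at days 6 to 12 (adjusted p = 0.273). LXLOC_000002, on the minus strand (1128 to 1631), stood at 158 ± 57.7 FPKM in later CN30 worms and 79.8 ± 28.2 in later N2 (0.96 ± 0.24, adjusted p = 0.0215). Within CN30 it rose by 1.22 ± 0.32 with age (adjusted p = 0.0126), as did LXLOC_000003, LXLOC_000004 and LXLOC_000005 on the same strand (adjusted p = 0.0113, 0.00271 and 0.0391), but with 0.43 ± 0.31 in N2 (adjusted p = 0.313) the difference in its rise, 0.79 ± 0.48, did not pass (adjusted p = 0.386). These minus-strand loci lie within the span of LXLOC_000001, whose plus-strand level is far higher. The higher antisense signal of later CN30 libraries, described above, thus limits these changes as well.

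Of 117 mRNA genes that differed between the strains in the same direction at day 0 and later, 68 did so by 1 or more on the log2 scale at both, 38 higher and 30 lower in CN30. Some of these overlap and share reads, or have equal values in every library; merged, they made 64 loci. The median distance to the nearest other locus was 285 kb, where 10000 random sets of merged loci had a median of 532 kb (permutation p = 0.0044, one-sided). This replaced a first test without merging, seen before it, which gave 246 kb against 488 kb (permutation p = 0.0033). Differences in nuclear DNA near these genes may account for such grouping, as may tandem families that share reads or neighbours that share control, which was not tested. In background knowledge, CB4856 lacks peel-1, carries a defective ppw-1, and N2 has a retrotransposon inserted in plg-1. Low ppw-1 and a low plg-1 locus in CN30 may go with a nucleus that is not wholly N2. RNA levels do not show which allele is carried, however, and this link was not tested. Whether the N2 signal over plg-1 came from that gene or from the inserted element is not told. A whole CB4856 nucleus is at odds with peel-1, whose lowest level in the day-0 CN30 libraries was 4.77 FPKM. The assembled locus MXLOC_000398 over ppw-1 did not pass at day 0 (log2 0.13 ± 0.07, adjusted p = 0.325), which limits what ppw-1 shows. The labels do not name the donors, so which stretches of the genome differ stays open.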
